A study of Caenorhabditis elegans with 8 samples.

How the data were processed

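The study measured RNA in cells sorted from L4 animals of Caenorhabditis elegans of 2 genotypes, wild type and skn-1gf(lax188), with 4 libraries each. Per the labels' protocols, large synchronised populations carrying daf-7p::gfp were dissociated with a detergent and reductant buffer and Pronase, strained, stained with DAPI for viability and sorted. The extraction protocol of the labels speaks of homogenised animals, so the step between the sort and the RNA isolation is described only in part. Libraries were made from total RNA with the Ovation SoLo kit, per the labels. The labels call the libraries biological replicates and say no more of their origin.

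Whole-number read counts per gene were deposited by the authors, 1 file per library, and were used as deposited. The submitters' processing notes name STAR 2.7.6a, HTSeq 2.0.2, DESeq2, R 3.5.2 and the build ce10. The strand setting of the counting, the annotation release and the handling of duplicates or molecular identifiers are not given in the sources used here. Reads of a gene and of an overlapping antisense gene therefore cannot be told apart, and intervals from counts cover counting error only. Each file held 46928 gene rows, of which 46919 locus tags were matched to symbols in a RefSeq gene table of the assembly WBcel235. That table was used for names, biotypes and the order of neighbouring genes only, and no coordinates were used because its assembly carries another name than the submitters' build. The 5 summary lines of each file stayed out of library sizes and tests. Reads with no feature were 2.76 to 14.4% and ambiguous reads 1.48 to 2.62% of the uniquely aligned reads. Multiply aligned reads were 12.3 to 30.3% of all counted reads, so that near-identical gene copies lost reads.

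Depth ranged from 2976889 to 10740970 gene counts per library. Ribosomal RNA genes took 7.26 to 33.9% of gene counts and protein-coding genes 63.0 to 91.2%. Ribosomal RNA genes stayed in the tested counts, and TMM factors ran from 0.658 (wild-type replicate 2) to 1.30 (wild-type replicate 3). Log2 CPM values of pairs of libraries correlated across genes with coefficients of 0.633 to 0.949. The first principal component held 46.6% of the variance and set wild-type replicate 2 apart, at 202 where the other libraries lay between −88.3 and 18.2.

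Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest) on genotype alone. The low-count filter was filterByExpr at its defaults (minimum count 10, minimum total 15), scaling was TMM, and p-values were adjusted by Benjamini-Hochberg over the 12734 genes that passed the filter, with a threshold of 0.05. Log2 CPM values used a prior count of 2. CPM values were counts scaled by the TMM-adjusted library size, and the SE of a fold change was derived from the same model. A gene with 0 counts in a genotype was set against a floor of 3 counts over the group.

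The 28 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists cover SKN-1 detoxification targets, proteasome subunits, RNA interference and small RNA factors, the intracellular pathogen response, innate immune effectors, heat shock chaperones, the endoplasmic reticulum unfolded protein response, nuclear and mitochondrial genes of electron transport, cytosolic ribosomal proteins, lipid metabolism, dauer, TGF-beta and insulin signalling, insulin-like peptides, neuropeptides, chemoreceptors, collagens and histones. Cell type lists cover ASI neurons, ciliated sensory neurons, pan-neuronal genes, intestine, body wall muscle, pharynx, hypodermis, germline and oocytes, sperm, glia and coelomocytes. Lists were written from general knowledge of the field, some genes stand in more than 1 list, and 3 names (mut-2, cde-1 and daf-21) were not matched. Lists with at least 3 tested members were compared with other genes by camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Means of the cell type lists per library were compared by a two-sided exact permutation test over 70 assignments, whose smallest p is 0.0286, with Benjamini-Hochberg adjustment over these lists. Members were also adjusted over each list alone, separately for each of the 28 lists. The fixed plan named adjustment over all genes only, and no correction was made for the number of lists. The rule names skn-1, drh-1 and daf-7, genes that pass the test, or where fewer than 5 pass in a direction the 5 with the smallest p as values, and up to 4 members of each list with the smallest p.

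The alternatives were DESeq2 1.42.0, limma-voom, other scalings (RLE, upper quartile, total counts), no filter or a stricter filter (1 CPM and 10 counts in 4 libraries), the replicate number as a block, protein-coding genes only, a fold threshold of 1.5 (glmTreat), robust dispersion, a covariate for neuronal against other transcripts, and each library left out in turn. DESeq2 was run without the low-count filter. The covariate, in log2 CPM, was the mean of the pan-neuronal and ciliated list means minus a mean of tissue list means. The tissues were intestine, body wall muscle, hypodermis, pharynx and germline. Added after seeing the data were limma-voom with sample quality weights, leaving out both libraries numbered 2, upper-quartile and total-count scaling of the list tests, the permutation test for the other lists and the counts of SKN-1, ASI and glia list members that pass under each setting. Exact correlations and outlier checks were computed with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

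The gene test was tested on simulated data for this comparison, with counts drawn for the 12734 genes from the real means, library sizes and dispersions and 200 genes changed in each of 5 runs. It called 1.2% of the genes changed 2-fold, 25.2% at 4-fold, 52.0% at 8-fold and 79.6% at 16-fold, and 25 of 62670 unchanged genes. In simulated lists, camera called a shifted list in 5 of 5 runs and 0 of 140 lists without a shift, in data without correlation between genes, and the exact permutation test was under 0.05 in 6 of 140.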

Results

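RNA was sequenced from sorted cells of Caenorhabditis elegans to compare wild-type (N2) animals with animals that carry skn-1gf(lax188), a gain-of-function allele of the gene for SKN-1, a transcription factor that activates detoxification and antioxidant genes. The sort used green fluorescent protein driven by the promoter of daf-7, which encodes a TGF-beta ligand made mainly by the ASI pair of chemosensory neurons. The series title places the question in these neurons and names a dicer-related helicase that counteracts harm from SKN-1 activity there. There were 8 libraries, 4 per genotype, labelled as biological replicates. Total gene counts were 7927544, 9652874, 5475892 and 10740970 in wild-type replicates 1 to 4, and 9680840, 6521589, 3622318 and 2976889 in skn-1gf replicates 1 to 4. Between 11909 genes (wild-type replicate 2) and 20394 genes (wild-type replicate 3) had at least 1 count. Values below are means ± SD over the 4 libraries of a genotype, as CPM, counts scaled by library size after TMM normalisation. Log2 fold changes are skn-1gf minus wild type, with their standard error (SE).

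Several glutathione S-transferase genes that SKN-1 is known to activate had higher mean levels in skn-1gf libraries. Transcripts of muscle, intestine and germline were abundant in these libraries, so the higher levels cannot be placed in ASI neurons. The smallest p in the list was that of gst-4 (CELE_K08F4.7), a widely used reporter of SKN-1 activity, at 10.5 ± 2.96 CPM in wild type and 76.9 ± 52.5 CPM in skn-1gf. The difference was 7.33-fold (log2 fold change 2.87, SE 0.50, 95% confidence interval 1.79 to 3.96). The related gst-30 (CELE_ZK546.11) was at 1.52 ± 1.30 and 27.4 ± 35.7 CPM (log2 fold change 4.14, SE 1.13). Its skn-1gf mean rested on replicate 1 (80.8 CPM, against 6.08 to 12.3 CPM in the others), without which the log2 fold change was 2.64. Of the 20 SKN-1 list members tested, 17 had a positive and 3 a negative log2 fold change, with a median of 0.99. No member passed with adjustment over all 12734 genes, where edgeR gave gst-4 an adjusted p of 0.999989. Adjusted over the list alone, 2 members passed, gst-4 (adjusted p = 0.00166 in edgeR) and gst-30 (adjusted p = 0.0321 in edgeR). DESeq2, run as an alternative without the low-count filter, gave gst-4 an adjusted p of 0.00087 over 24261 genes. Here both the method and the gene set differed from edgeR's. Over all alternatives the adjusted p of gst-4 ran from 1.91e-05 to 0.999988. The count adjusted over the list alone was 1 without skn-1gf replicate 1 or without wild-type replicate 3, and 6 without skn-1gf replicate 2. It included gst-4 in all 3 cases, and gst-30 was lost in the first 2.

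In 4 members, every skn-1gf library lay above every wild-type library, where chance gives 2.86% of genes a full separation in either direction. These were gst-4, gst-30, gst-14 (0.552 ± 0.503 against 3.94 ± 3.21 CPM) and gcs-1 (76.5 ± 3.42 against 117 ± 40.7 CPM), which encodes the enzyme that limits glutathione synthesis. The latter pair, gst-14 and gcs-1, lay outside the naming rule and was chosen after the values were seen. For gst-14 the separation was close to a tie, with 1.216 CPM in skn-1gf replicate 2 and 1.215 CPM in wild-type replicate 4. With overlap between the genotypes, gst-7 had a log2 fold change of 1.11 (SE 0.38) and gst-5 one of 1.69 (SE 0.58), which were 0.710 and 0.858 without skn-1gf replicate 1. The list mean was 3.04 ± 0.337 log2 CPM in wild type and 4.01 ± 0.911 in skn-1gf. This difference of 0.966 was not separated from the replicate spread (two-sided exact permutation p = 0.114). The camera test, which sets the list against all other genes at a preset inter-gene correlation, called it (adjusted p = 5.31e-05). That call was lost with an estimated correlation (adjusted p = 0.727 with an estimated correlation). Marker lists of glia and of ASI neurons were also higher in skn-1gf, by 1.27 and 1.32 log2 units. With single libraries left out these differences fell to as little as 0.614 and 0.726. Neither list passed the permutation test, in which a list could not pass on its own after adjustment over the cell type lists.

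**Figure D1:**
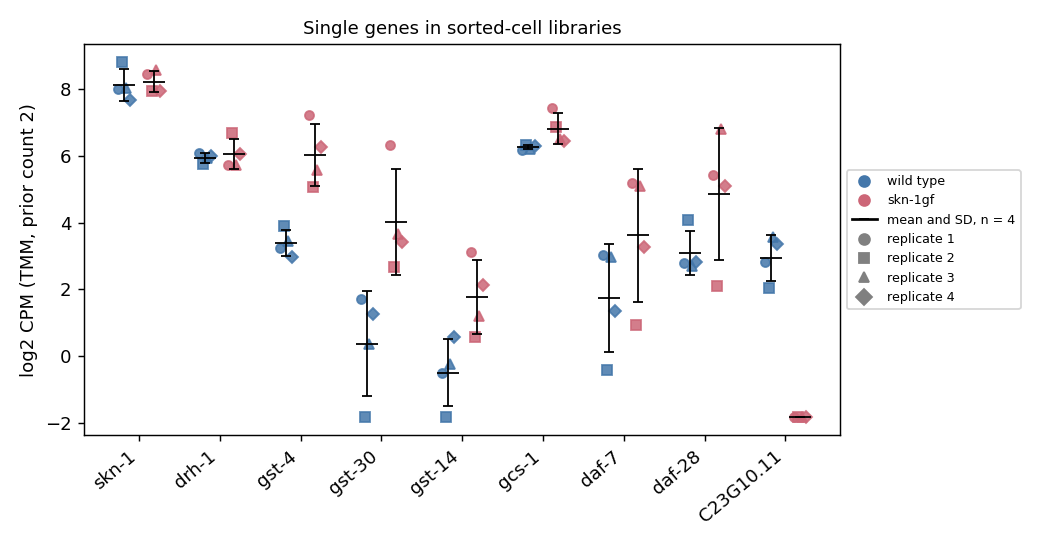
Level of 9 genes in each library, as log2 CPM with a prior count of 2, in wild type (blue) and skn-1gf (red), with replicate numbers as marker shapes and lines for the mean and SD of 4 libraries. The skn-1gf libraries lie above all wild-type libraries for gst-4, gst-30, gst-14 and gcs-1 and below them for C23G10.11, while those of skn-1, drh-1, daf-7 and daf-28 overlap. The margin for gst-14 is close to a tie, at 0.581 log2 CPM in skn-1gf replicate 2 and 0.580 in wild-type replicate 4.

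No difference in the RNA of skn-1 (CELE_T19E7.2) itself was detected. It was at 295 ± 108 CPM in wild type and 307 ± 68.6 CPM in skn-1gf (log2 fold change 0.06, SE 0.31, 95% confidence interval −0.61 to 0.72). The sign turned with total-count scaling (−0.01) and without wild-type replicate 4 (−0.08) or skn-1gf replicate 3 (−0.04). A gain-of-function allele need not alter the RNA level of its gene, so this value does not check the genotype labels. For drh-1 (CELE_F15B10.2), a dicer-related helicase of the antiviral RNA interference pathway, levels were 61.9 ± 6.17 and 68.9 ± 23.6 CPM. Its log2 fold change was 0.16 (SE 0.30, 95% confidence interval −0.50 to 0.81) and turned negative without skn-1gf replicate 2 (−0.12) and with both libraries numbered 2 left out (−0.18). Sample quality weights in limma-voom gave −0.08, and these last 2 settings were chosen after seeing the data. The gene whose promoter marked the sort, daf-7 (CELE_B0412.2), was at 7.98, 0.474, 7.52 and 2.27 CPM in wild-type replicates 1 to 4. In skn-1gf replicates 1 to 4 it was at 36.1, 1.62, 34.1 and 9.36 CPM. Its log2 fold change of 2.15 (SE 1.01, 95% confidence interval −0.04 to 4.33) did not pass the test.

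Outside these lists, the genes with the smallest p are given as values and not called changed. Above every wild-type library in all 4 skn-1gf libraries were har-1 (CELE_C16C10.11), which encodes a mitochondrial CHCH-domain protein, Y54G2A.18 and try-14 (CELE_F48E3.4). Mean levels were 75.5 ± 14.7 against 198 ± 65.4 CPM for har-1, 73.9 ± 24.9 against 186 ± 19.01 CPM for Y54G2A.18, and 96.2 ± 23.1 against 269 ± 135 CPM for try-14. ZC373.2 had a log2 fold change of 3.72 (SE 0.96) with overlap between the genotypes, its mean resting on 1 skn-1gf library (425 ± 676 CPM). In the other direction, C23G10.11 had 64, 24, 82 and 123 counts in wild-type replicates 1 to 4 and 0 counts in all skn-1gf libraries. Set against a floor of 3 counts over the group (0.137 CPM), it was at least 58.9-fold lower. M28.4 had 275 counts in wild type and 2 in skn-1gf, a ratio of 92.8 per total gene count (95% exact interval 25.4 to 769.8). Wild-type replicate 2 held 198 of the 275 counts, and without it the ratio was 36.4 (interval 9.73 to 305.6). Also below every wild-type library were F45D3.4 (103 ± 28.37 against 29.6 ± 13.2 CPM), srlf-34 (40.8 ± 26.5 against 7.14 ± 3.55 CPM) and mpst-4, a sulfurtransferase gene (28.3 ± 39.2 against 1.32 ± 0.642 CPM). The wild-type mean of mpst-4 rested on replicate 2 (86.5 CPM), without which its log2 fold change went from −4.44 to −2.76. Floors and count intervals cover counting error only.

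Over all 12734 genes tested, edgeR's quasi-likelihood test called 0 genes at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 518 genes, 184 with higher and 334 with lower values in skn-1gf, where chance gives 636.7. DESeq2, run on 24261 genes without the low-count filter, called 3 genes, gst-4 with a higher and C23G10.11 and mpst-4 with a lower level. On the 12734 genes limma-voom called 0. Without a low-count filter edgeR called 159 genes, and limma-voom with sample quality weights called 6. All libraries of one genotype were separated from all of the other in 276 genes, 129 with skn-1gf above and 147 below, and chance gives 363.8. The biological coefficient of variation was 0.707 and the median 95% interval of a log2 fold change extended 1.44 to either side, so that a 2-fold difference in a typical gene was not detectable.

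Transcripts of marker genes for tissues other than ASI neurons were abundant in the libraries of both genotypes. The 8 ASI marker genes together took between 0.00132% (wild-type replicate 4, 95% Clopper-Pearson interval 0.00110 to 0.00158%) and 0.0201% of protein-coding counts (skn-1gf replicate 3, interval 0.0186 to 0.0218%). Body wall muscle markers took 1.27 to 4.67%, intestine markers 0.305 to 3.11% and germline and oocyte markers 1.105 to 2.65%. Single muscle genes were far above daf-7, such as act-4 at 2556 ± 828 CPM in wild type and 5914 ± 3183 CPM in skn-1gf, and the paramyosin gene unc-15 at 1872 ± 357 and 3004 ± 1556 CPM. Of the ASI markers, 5 passed the low-count filter, and str-3, gpa-5 and str-2 did not. The highest was daf-28, an insulin-like peptide gene, at 9.10 ± 5.11 and 48.1 ± 45.2 CPM (95% confidence interval of the log2 fold change 0.72 to 4.08), the 1 ASI member to pass when adjusted over the list alone (adjusted p = 0.0448 in edgeR). It no longer passed with limma-voom, with upper-quartile scaling, with a fold threshold, with the replicate block, or without any 1 of wild-type replicates 1, 3 and 4 and skn-1gf replicates 1, 3 and 4 (smallest adjusted p of the list 0.0543 to 0.336 in edgeR without single ones of these), and its log2 fold change was 1.58 without skn-1gf replicate 3. Other settings gained members. With the replicate block daf-7 and ins-6 passed over the list alone, and with DESeq2 daf-28 and ins-6 passed. All of daf-7, daf-28 and ins-6 passed without skn-1gf replicate 2, with both libraries numbered 2 left out and, along with str-3, without the low-count filter. The call of str-3 went the other way and rested on 1 library, with 39 counts in wild-type replicate 2 and 0 in every other library. In the main analysis none passed over all genes. Of the others, ins-6 was at 0.998 ± 0.888 and 7.85 ± 7.82 CPM.

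None of the 11 cell type lists was called by the exact permutation test of list means (smallest adjusted p = 0.707). With 70 assignments the smallest unadjusted p is 0.0286, so a list could not pass on its own after adjustment over 11 lists. The test therefore cannot show that the cell types were equally represented in both genotypes. The ASI list mean was 1.14 ± 1.25 log2 CPM in wild type and 2.46 ± 1.29 in skn-1gf, with 4 of 5 members higher. Ciliated sensory neuron genes, among them the intraflagellar transport gene xbx-1 and che-12, were at 1.40 ± 1.41 and 2.20 ± 0.991, with 30 of 36 members higher. With single libraries left out the ciliated list difference ran from 0.148 to 1.31. For pan-neuronal genes such as egl-21 and snb-1 the means were 4.79 ± 1.11 and 5.09 ± 1.21, with 20 of 27 members higher, and the sign of their difference turned without wild-type replicate 2 (−0.0774) or skn-1gf replicate 3 (−0.00539). Glia markers were at 2.37 ± 1.25 and 3.64 ± 1.24 with all 6 members higher, and spig-11 and fig-1 passed when adjusted over the list alone (adjusted p = 0.0491 in edgeR for both). Neither passed with DESeq2, limma-voom, any other scaling or without skn-1gf replicate 3 (smallest adjusted p = 0.454 in edgeR), where their log2 fold changes were 0.819 and 0.914, and leaving out skn-1gf replicate 1 or any wild-type library also ended both calls, with fig-1 lost without skn-1gf replicate 4. Coelomocyte markers were at 5.14 ± 0.488 and 5.83 ± 0.545 with all 3 members higher, including unc-122 and cup-4. Sperm markers were at 5.09 ± 1.47 and 3.78 ± 1.39 with 42 of 43 members lower, for example gsp-3 at 76.9 ± 72.8 and 16.50 ± 9.61 CPM and msp-42, annotated as a pseudogene, at 3.26 ± 2.34 and 0.255 ± 0.353 CPM. These members varied together (estimated correlation 0.840), so their number is not a number of independent results. In wild type the sperm mean ran from 3.28 (replicate 3) to 6.44 (replicate 2). With single libraries left out the sperm difference ran from −1.98 to −0.714.

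Of the remaining tissue lists, body wall muscle had a difference of 0.230 log2 units, intestine 0.122, pharynx 0.345, hypodermis −0.664, and germline and oocyte −0.00440. With single libraries left out the intestine difference ran from −0.129 (without skn-1gf replicate 1) to 0.877 (without skn-1gf replicate 2), pharynx from −0.308 (without skn-1gf replicate 3) to 1.08 and germline from −0.152 to 0.189. Body wall muscle ran from 0.0685 to 0.622 and hypodermis from −0.919 to −0.0531. Among their members, the vitellogenin gene vit-3 had a log2 fold change of 0.98 (SE 0.63). The pharyngeal gland gene phat-6 was at 10.05 ± 5.81 and 26.6 ± 17.6 CPM. The eggshell genes perm-4 and perm-2 had log2 fold changes of 1.94 (SE 0.55) and 1.92 (SE 0.56) within a germline list whose median was −0.11. None of these genes passed the test. Multiply aligned reads were not assigned to genes, so values of near-identical family members (msp, his, vit and ribosomal protein genes) are uncertain.

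**Figure D2:**
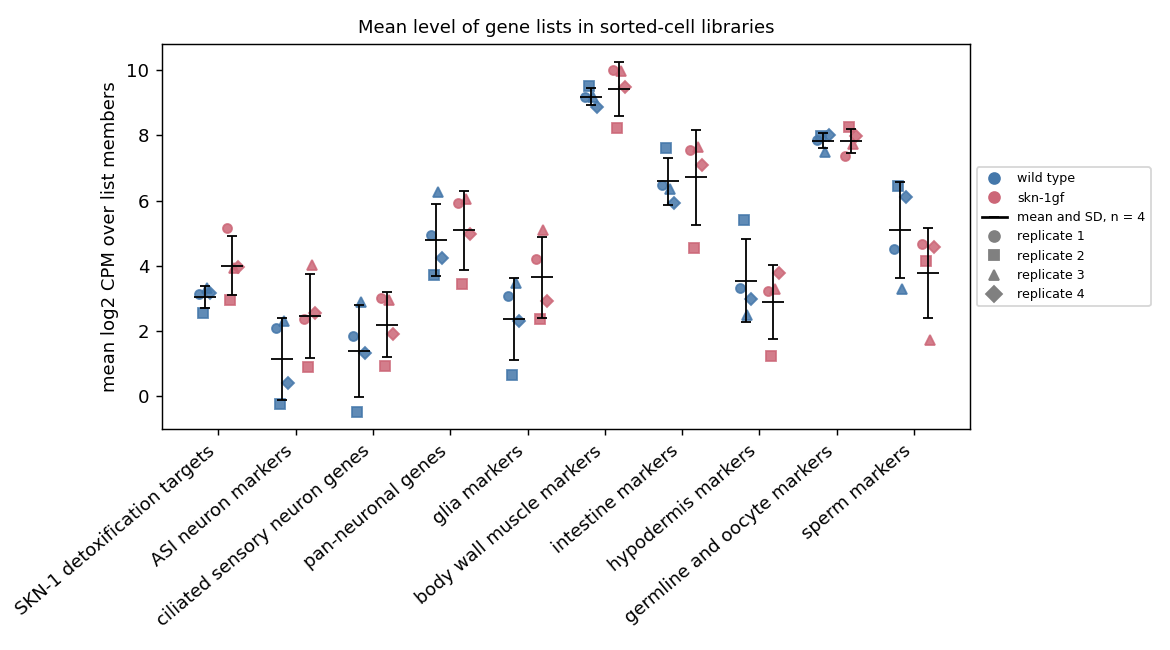
Mean log2 CPM over the tested members of 10 gene lists in each library, in wild type (blue) and skn-1gf (red), with replicate numbers as marker shapes and lines for the mean and SD of 4 libraries. Muscle, intestine and germline lists lie above the ASI, ciliated and pan-neuronal lists in all 8 libraries, and the genotypes overlap in every list, with the SKN-1 targets at 3.04 ± 0.337 and 4.01 ± 0.911.

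Among the secreted signals and receptors of neurons, insulin-like peptides had the largest difference. Their list mean was 1.40 ± 0.617 log2 CPM in wild type and 2.56 ± 1.32 in skn-1gf, with 14 of 16 members higher. Besides daf-28 and ins-6, ins-27 was at 7.34 ± 3.61 and 24.9 ± 12.98 CPM, above every wild-type library in all skn-1gf libraries. Neuropeptide genes had 75 of 95 members higher and a mean difference of 0.294. The antimicrobial-type neuropeptide genes nlp-31 (30.9 ± 13.3 against 9.54 ± 6.22 CPM) and nlp-30 (21.03 ± 17.7 against 5.75 ± 5.31 CPM), expressed in the epidermis, went the other way. Chemoreceptors had 24 of 1628 genes above the low-count filter and a difference of 0.283, with sri-40 at 52.4 ± 7.74 and 117 ± 47.1 CPM. The dauer, TGF-beta and insulin signalling list had a difference of 0.151, with the kinase gene akt-2 at 26.8 ± 15.1 and 16.21 ± 7.49 CPM. No member of these 4 lists passed over all genes, and 0 passed when adjusted over the list alone.

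Collagens had 91 of 111 members lower in skn-1gf and a difference of list means of −0.715, led by rol-6 (87.4 ± 139 against 5.63 ± 5.39 CPM) and col-90 (19.04 ± 34.7 against 1.59 ± 1.75 CPM). This rested on the libraries numbered 2, since the collagen difference was −0.02 without wild-type replicate 2, 0.02 without skn-1gf replicate 2 and 0.71 with both left out, where col-90 also turned to 0.15. For rol-6 the log2 fold change went from −3.96 to −1.71 without wild-type replicate 2. Histones had 29 of 39 members lower (−0.304), with his-45 at 117 ± 157 and 17.5 ± 4.60 CPM (log2 fold change −2.73, and −1.18 without wild-type replicate 2), while his-72, a replication-independent H3 gene, was at 94.0 ± 10.5 and 168 ± 52.8 CPM. Their difference turned to 0.05 without wild-type replicate 2 and to 0.08 with both libraries numbered 2 left out.

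Nuclear genes of mitochondrial electron transport had 26 of 30 members higher, with a small mean difference of 0.253 (0.0723 to 0.427 with single libraries left out). Examples were the complex II genes sdhd-1 (64.2 ± 17.96 against 114 ± 27.1 CPM) and mev-1 (76.7 ± 18.03 against 117 ± 15.1 CPM). Genes of the mitochondrial genome varied widely within skn-1gf, taking 9.67, 0.751, 1.00 and 4.61% of protein-coding counts in replicates 1 to 4, against 1.75 to 2.75% in wild type. Their list difference was 0.220 with nduo-2 at 272 ± 48.5 and 764 ± 870 CPM. Cytosolic ribosomal proteins had a difference of −0.0790 with 53 of 77 members lower, and rps-29 at 490 ± 95.2 and 828 ± 333 CPM went the other way. Proteasome subunits, targets of SKN-1 upon proteasome impairment, had a difference of −0.0575 with 21 of 32 members lower, and pbs-1 was at 153 ± 42.4 and 236 ± 76.1 CPM.

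RNA interference and small RNA factors were at 6.05 ± 0.106 log2 CPM in wild type and 5.86 ± 0.370 in skn-1gf, with 30 of 45 members lower. The spermatogenesis Argonaute genes alg-4 (81.8 ± 91.7 against 14.4 ± 10.3 CPM) and alg-3 (63.1 ± 53.0 against 16.8 ± 11.9 CPM) had the lowest p, with log2 fold changes of −1.33 and −1.18 without wild-type replicate 2, and sperm markers had lower means in the same genotype. The microRNA Argonaute gene alg-2 was at 41.2 ± 7.04 and 62.7 ± 19.8 CPM. The intracellular pathogen response list had 5 of 26 genes above the filter and a difference of −0.345, with skr-3 at 15.9 ± 5.78 and 35.4 ± 20.3 CPM and pals-26 at 5.40 ± 3.53 and 1.64 ± 2.27 CPM. Innate immune effectors had a difference of 0.341, with 11 of 14 members higher and nlp-29 lower (65.9 ± 28.2 against 30.6 ± 16.3 CPM). Heat shock chaperones had a difference of −0.296, with F44E5.5 at 7.47 ± 4.71 and 3.21 ± 1.40 CPM and hsp-12.6 at 4.45 ± 2.86 and 1.83 ± 1.46 CPM. The endoplasmic reticulum unfolded protein response list had 14 of 16 members higher and a difference of 0.295 (exact permutation p = 0.0571), with the disulfide isomerase gene pdi-6 at 98.0 ± 7.32 and 130 ± 42.8 CPM. Lipid metabolism genes had a mean difference of −0.0917 but a median log2 fold change of 0.03, with the SREBP gene sbp-1 at 14.7 ± 10.8 and 29.99 ± 16.3 CPM. In the lists from collagens to lipid metabolism, 0 members passed over all genes or when adjusted over the list alone. The sign of the uncalled differences of proteasome, pathogen response, mitochondrial genome, ribosomal protein, lipid metabolism, dauer signalling, neuropeptide and chemoreceptor lists turned when single libraries were left out.

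By camera with its preset correlation, 9 of the 28 lists were called. Adjusted p-values were 5.31e-05 for SKN-1 targets, 6.1e-05 for insulin-like peptides, 0.0009 for ciliated neuron genes, 0.00411 for glia, 0.00704 for nuclear electron transport genes, 0.0250 for ASI markers and 0.0370 for coelomocytes, all with higher levels in skn-1gf. Sperm markers (1.64e-11) and collagens (0.000167) were called with lower levels. All 9 calls were lost with an estimated correlation (adjusted p = 0.727 to 0.879 with an estimated correlation), and fry called 0 lists. Other divisions of the 8 libraries into groups of 4 called as many lists in most cases, with 30 of all 35 divisions reaching 9 or more. An exact permutation test of the list means called 0 of the lists that are not cell types (smallest adjusted p = 0.941), a test added after seeing the data. After adjustment over these lists, a list at the smallest possible p could not pass on its own, so this count decides little. The count of called lists was 6 without skn-1gf replicate 1 and 18 without skn-1gf replicate 2. Leaving out 1 library ended the calls of nuclear electron transport genes (wild-type replicate 1 or 3 or skn-1gf replicate 1), collagens (replicate 2 of either genotype), ASI markers (wild-type replicate 4 or skn-1gf replicate 3), ciliated neuron genes (wild-type replicate 2 or skn-1gf replicate 1), glia (skn-1gf replicate 3) and coelomocytes (wild-type replicate 1 or 3 or skn-1gf replicate 1 or 2). Total-count scaling also ended the coelomocyte call, and with both libraries numbered 2 left out collagens were called in the opposite direction, with higher levels in skn-1gf.

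**Figure D3:**
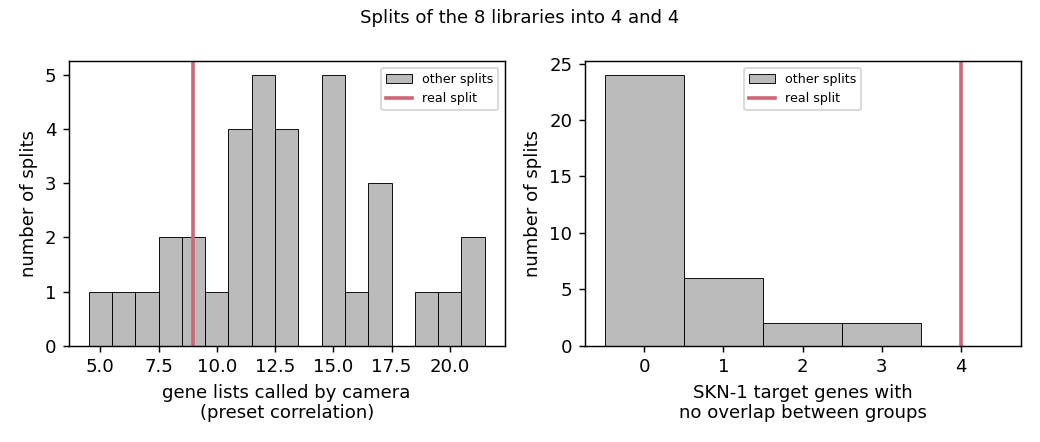
Left, number of gene lists called by camera at its preset correlation, and right, number of SKN-1 target genes with no overlap between groups, in divisions of the 8 libraries into 4 and 4 (bars count the 34 other divisions, the red line is the real division). The real division called 9 lists, where others called up to 21, and had 4 SKN-1 target genes without overlap, where others had at most 3, a count chosen after the values were seen. Among these 4, gst-14 was close to a tie (1.216 CPM in skn-1gf replicate 2, 1.215 CPM in wild-type replicate 4).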

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

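Tests chosen only after the results were seen were the count of SKN-1 members without overlap over divisions of the libraries, the comparison of muscle, intestine and germline lists with the ASI list, and the divisions for the counts of called genes and of genes called with sample quality weights. In 9 of 192 groups of 4 libraries, 1 library lay far from the other 3, where chance gives 9.6. Wild-type replicate 2 accounted for 4 of them. Its share of ribosomal RNA was 33.9% where the others had 8.94 to 11.99%, and its share of protein-coding counts was 63.0% against 86.1 to 89.3%. In log2 CPM, its daf-28 was at 4.09 against 2.71 to 2.82, and its rol-6 at 8.21 against 4.03 to 4.36. In skn-1gf replicate 2, F45D3.4 was at 3.38 against 5.07 to 5.31 and mev-1 at 6.56 against 6.94 to 6.97. The RNA interference list was at 5.89 in wild-type replicate 3 against 6.08 to 6.11, try-14 at 7.03 in wild-type replicate 1 against 6.37 to 6.48, and gst-7 at 6.69 in wild-type replicate 4 against 5.71 to 5.84.

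The SKN-1 target list was higher in skn-1gf by 0.966 log2 units (SE 0.486), with 4 members free of overlap. Lower sequencing depth of the skn-1gf libraries is argued against, since thinning every library to 2966740 counts left a difference of 0.879 (SD 0.0328 over 20 draws). Chance is not excluded, because 4 of 35 divisions of the libraries matched the list mean, and the 4 members without overlap, reached in 1 of 35 divisions with a highest other of 3, are a count chosen after these members had been seen. That count includes gst-14, which was close to a tie (1.216 CPM in skn-1gf replicate 2, 1.215 CPM in wild-type replicate 4). The lead of the count over other divisions rests on that margin. A different share of neuronal RNA stays open. With the covariate for neuronal against other lists the difference was 0.828 (SE 0.493). This is too imprecise to exclude a value under 0.483, the limit that follows from the prediction written before this test. The covariate is a difference of list means and not a share of RNA. It gave skn-1gf replicate 2 −2.69, close to wild-type replicate 1 (−2.73), although their pan-neuronal means were 3.43 and 4.94 log2 CPM. Whether 1 library carries the difference stays open as well, because without skn-1gf replicate 1 it was 0.539 (SE 0.346); the genotype remains an untested biological explanation beside these.

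No gene passed the adjusted threshold in edgeR, although 25.2% of simulated 4-fold changes were called with the same numbers of libraries. Without the outlying wild-type replicate 2, 0 genes passed. With the covariate for neuronal against other lists, which stood for a varying share of neuronal RNA, 0 passed as well. Both counts went against the predictions for these explanations. Neither explanation is excluded, because leaving out a library or adding a covariate also lowers the power of the test. Divisions of the libraries are uninformative for a count of 0, which all 35 of 35 reach with a highest other of 0. At an unadjusted p under 0.05, 11 of 35 divisions gave at least the real 518 genes and the highest other gave 2197, which points to a structure of the samples other than genotype alone. That division set wild-type replicates 1, 2 and 4 and skn-1gf replicate 2 against the rest. The rest had higher pan-neuronal means (4.97 to 6.28 against 3.43 to 4.94 log2 CPM) and ASI means (2.31 to 4.03 against −0.235 to 2.09). They included most skn-1gf libraries, so this structure is not independent of genotype. These lists were compared after the values were seen, and no cause was tested.

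Transcripts of muscle, intestine and germline were abundant in libraries from a sort for daf-7p::gfp cells, with act-4 at 2556 CPM and unc-15 at 1872 CPM in wild type against 4.56 CPM for daf-7. The median level of each of these 3 lists was above the ASI median in 8 of 8 libraries. This restates the pattern and by itself decides nothing on RNA of other cell types in the sorted material. The vitellogenin gene vit-5 (1653 CPM) and the eggshell gene perm-2 (1050 CPM) were abundant in wild type too. How these transcripts came into the libraries stays open. A sort gate on green cells and on viability would remove cells of these tissues. Free RNA from dissociated tissue, imperfect gating or RNA taken before the sort could each give these values, and none of them was tested. Low levels of the 5 tested ASI markers per cell would also place them below muscle genes. Such low levels alone would not account for the high levels of the muscle, intestine and germline genes. Means of these 3 lists were above the pan-neuronal mean in 8 of 8 libraries as well. None of the genes of these 3 lists stands in another list, how many of them ASI neurons also express was not tested, and no biological explanation was tested.

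The counts of the camera test, of edgeR without a low-count filter and of limma-voom with sample quality weights were also within reach of chance. The 9 lists called by camera were matched or exceeded in 30 of 35 divisions, with a highest other of 21. The 159 genes called without a low-count filter were matched or exceeded in 10 of 35 divisions, with a highest other of 704, and the 6 genes called with sample quality weights in 4 of 35, with a highest other of 121.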

How the results depend on the processing

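Leaving out both libraries numbered 2, sample quality weights, upper-quartile and total-count scaling for lists, the permutation test of lists that are not cell types and the SKN-1, ASI and glia counts by setting were chosen after seeing the data. The count of 0 genes became 3 (1 higher, 2 lower) with DESeq2, 159 (51 higher, 108 lower) without the low-count filter and 6 (5 higher, 1 lower) with sample quality weights. DESeq2 was run on 24261 genes without the low-count filter, so that method and gene set changed together. The count stayed at 0 with limma-voom, RLE, upper quartile, total counts, the stricter filter, protein-coding genes, glmTreat, robust dispersion, the neuronal covariate, each library left out and both libraries numbered 2 left out. Genes at an unadjusted p under 0.05 in edgeR did move, from 518 of 12734 in the main analysis. They were 1528 of 13090 with both libraries numbered 2 left out (smallest adjusted p = 0.183 in edgeR). With single libraries left out they ran from 313 (without skn-1gf replicate 3) to 974 (without skn-1gf replicate 2). SKN-1 members passing when adjusted over the list alone were 2 in the main analysis, 7 with DESeq2 and with quality weights, 6 without the filter, 8 with both libraries numbered 2 left out, 1 with limma-voom, upper quartile, total counts or the neuronal covariate, and 1 to 6 with single libraries left out, and gst-4 was among them in every setting run. Total-count scaling moved the median log2 fold change of all genes from 0.04 to −0.12 and turned skn-1 (−0.0115), and no scaling turned a list. Quality weights turned drh-1 (−0.0788), and leaving out both libraries numbered 2 turned drh-1 (−0.176), col-90 (0.154), lipid metabolism (0.445), collagens (0.710), histones (0.0813) and hypodermis (0.479). Lists called by camera were 9, became 0 with an estimated correlation, 0 with fry, 0 by permutation for lists that are not cell types and 17 without both libraries numbered 2, and ran from 6 to 18 with single libraries left out. The permutation test of cell type lists called 0 lists in every setting run. This cannot show stability, because after adjustment a list could not pass on its own in any of them. With both libraries numbered 2 left out, or with sign flips within replicate numbers, the smallest possible p was itself over 0.05. Ranges over single left-out libraries that crossed 0 were −0.0814 to 0.310 for skn-1, −0.116 to 0.303 for drh-1, −0.255 to 0.0818 for proteasome, −0.547 to 0.166 for the pathogen response, −0.504 to 0.853 for the mitochondrial genome, −0.255 to 0.0700 for ribosomal proteins, −0.269 to 0.322 for lipid metabolism, −0.0572 to 0.388 for dauer signalling, −0.0912 to 0.998 for neuropeptides, −0.0941 to 0.450 for chemoreceptors, −1.09 to 0.0184 for collagens, −0.574 to 0.0546 for histones, −0.0774 to 0.845 for pan-neuronal genes, −0.129 to 0.877 for intestine, −0.308 to 1.08 for pharynx and −0.152 to 0.189 for germline. The cause of these changes was not tested. With the replicate block, 0 genes passed (679 at an unadjusted p under 0.05) and camera called 8 lists, 7 of them among the main 9. Same-numbered libraries had residual correlations of −0.01, 0.06, 0.51 and 0.06, and 1 of 4 wild-type libraries correlated best with its own number. The main test did not use the numbers as pairs, a choice fixed before the data were examined because they are labelled only as biological replicates. The median SE of a single gene was 0.66 log2 units.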

Other observations

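The correlations below were chosen after the data had been seen. Across the 8 libraries, list means of pan-neuronal genes were compared with 5 other lists, each with a two-sided exact permutation p and its adjustment over the 5 relations. Ciliated sensory neuron genes went with pan-neuronal genes (Pearson r = 0.912, exact p = 0.00186, adjusted 0.0093). Their Spearman rho was 0.881 (exact p = 0.00724, adjusted 0.0181), and r was 0.954 without the 2 libraries farthest from the median, wild-type replicate 3 and skn-1gf replicate 2. ASI markers had r = 0.824 (exact p = 0.0144, adjusted 0.0240), a rho of 0.762 (exact p = 0.0368, adjusted 0.0613) and r = 0.919 without that pair. Germline and oocyte markers went the opposite way, with r = −0.878 (exact p = 0.00387, adjusted 0.00967), a rho of −0.881 (exact p = 0.00724, adjusted 0.0181) and r = −0.765 without the pair. Body wall muscle, with r = 0.663 (exact p = 0.0711, adjusted 0.0744), a rho of 0.548 (exact p = 0.171, adjusted 0.197) and r = 0.707 without the pair, did not pass. Sperm markers did not pass either, with r = −0.657 (exact p = 0.0744, adjusted 0.0744), a rho of −0.524 (exact p = 0.197, adjusted 0.197) and r = −0.845 without the pair. No correlation was computed within a genotype, which holds only 4 libraries.

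The SKN-1 targets took 0.0674 to 0.0718% of protein-coding counts in the wild-type libraries and 0.160, 0.0815, 0.0805 and 0.0797% in skn-1gf replicates 1 to 4, so that all skn-1gf libraries lay above all wild-type libraries on this summed scale, which abundant members dominate. No test was run on it. Members that SKN-1 is also known to activate but that encode reductases of thioredoxin and glutathione, trxr-1 (126.4 ± 19.1 against 123 ± 30.1 CPM) and gsr-1 (139 ± 49.5 against 141 ± 22.9 CPM), differed by less than their replicate spread, as did aip-1 (36.1 ± 5.36 against 35.8 ± 7.89 CPM). These 3 were picked after their values were seen.

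In the order of the WBcel235 gene table, C23G10.2 and esyt-2, near the gene without counts in skn-1gf (C23G10.11), had log2 fold changes of 0.08 (SE 0.35) and 0.33 (SE 0.36). Its neighbours C23G10.1 and hot-4 had −2.13 and −1.13 with SEs over 1. The genes around M28.4 included M28.9 at −1.82 (SE 0.89) and M28.10 at 1.94 (SE 1.13). None of these neighbours passed the test, and no explanation was tested.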
